A study of Mus musculus with 10 samples.

How the data were processed

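Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on 3T3-L1 cells, a mouse fibroblast line that can be differentiated into adipocytes in culture. The series holds 10 samples, each a single library. Acetylation of histone H3 lysine 9 (H3K9ac) was profiled at 0, 24 and 240 h of differentiation, the transcription factor C/EBPβ at 0 and 6 h, and the glucocorticoid receptor (GR) at 6 h. The other 4 samples are input libraries at 0, 6, 24 and 240 h, which were not analysed here. The group and time of each sample were taken from its title.

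Per the labels' protocols, reads of 36 bp came from the Solexa pipeline and were placed on the mouse genome (mm8) by ELAND with up to 2 mismatches, and uniquely placed reads were kept with 1 read per start coordinate. Such reads leave repeats uncovered, and the limit of 1 read per start caps the height of the strongest peaks. The peak caller, its threshold and its use of the input libraries are not given in the sources used here. Each deposited C/EBPβ and GR list gives the position of every peak, its fold enrichment (a ratio over a background that is not described) and its peak height, a whole-number read signal whose lowest listed value is 12 in all 3 lists. Each deposited H3K9ac list gives only regions outside transcription start sites that the authors called differentially enriched at that time relative to another time, per the labels. For each such region the authors gave a false discovery rate (FDR), listed in a few steps with the lowest written as 0, and an average read count, a whole-number read signal. All H3K9ac boundaries fell on a 50 bp grid. The lists give no read totals, so the depth of each library is unknown, and a region missing from a list is not shown to lack signal. A further deposited file names 6 regions of input bias, 688 kb in all. None of the listed peaks or regions overlapped them, against 5.45 C/EBPβ peaks at 6 h if peaks were spread by length alone.

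Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No 2 intervals within a list overlapped, so no merging was needed. Peak lists were compared by overlap of at least 1 bp. An H3K9ac region counted as near a peak when the gap between them was under 1 kb. Coordinates are printed as deposited, on mm8. Shares are given with 95% Wilson intervals and differences of shares with 95% Newcombe intervals. Both cover counting error only. They describe these lists and not the spread between cultures, since every factor and time is 1 library and no p-value across libraries can be had. Overlaps of whole factor lists with each other, shares of H3K9ac regions near factor peaks, and shares of C/EBPβ and GR peaks near H3K9ac regions were also compared with 1000 random rotations of the second list along its chromosomes, with the highest listed coordinate as the chromosome length. The fold over random is the observed count divided by the mean of the rotations. Rotation can place peaks on repeats and on DNA where no factor binds, which raises the folds. Peaks were ranked by the authors' peak height, then fold enrichment, and H3K9ac regions by average read count, then FDR, always within a list. Remaining ties kept the order of the list. Fold enrichment, height, average read count and FDR are the authors' values and were used within a list. The exception is the draws of H3K9ac regions matched between lists, which also used average read count.

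The overlap and rotation code was tested on simulated lists. Lists with 5.03%, 20.09% and 60.21% of peaks planted on C/EBPβ 6 h peaks gave back those shares. Unplanted peaks that the same code placed on C/EBPβ peaks had been removed first, so this shows only that planted overlaps are found. The 4007 GR peaks were also set against 200 random rotations of the C/EBPβ 6 h list with a window of 1 kb, of which 3.5% fell outside the central 95% of 1000 other rotations.

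The overlaps, the ranking, the alternatives and the rule for named regions were fixed before the data were examined. Named regions are the 5 strongest of each list, the 3 strongest GR peaks that overlap a C/EBPβ 6 h peak near an H3K9ac 24 h region, and the 3 windows of 100 kb with most C/EBPβ 6 h peaks, GR peaks and H3K9ac 240 h regions. The split of C/EBPβ 6 h peaks by their presence at 0 h and by GR was added after the data had been examined. Added then too were the splits of C/EBPβ 0 h and GR peaks by the C/EBPβ 6 h list. The splits of H3K9ac regions by read count and by the 6 h factors near them were also added then. So were the height classes for the overlap of C/EBPβ 6 h peaks and of GR peaks with the C/EBPβ 0 h list, the ranking by fold enrichment, the distances between H3K9ac lists and the counts by chromosome. Alternatives covered the overlap required, the distance, the stronger peaks of each factor list (those ranked above its median), autosomes alone, equal list lengths, uniform random placement and 10 height classes in place of 4. Gene lists had been drawn up in advance, but the deposited lists name no genes, and the gene table at hand is on another assembly (GRCm38), so genes were not analysed here and regions are identified by position. H3K9ac signal of 1 region at the other times was not analysed here either, since each list gives its own time only.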

Results

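The data consisted of 6 region lists from differentiating 3T3-L1 preadipocytes. C/EBPβ, a basic leucine zipper factor that acts early in adipocyte differentiation, had 10359 peaks in undifferentiated cells (0 h) and 20746 peaks 6 h after induction. GR, the nuclear receptor for glucocorticoids, which are commonly part of adipogenic hormone mixtures, had 4007 peaks at 6 h. H3K9ac, a histone mark found at active regulatory DNA, was listed only where it was differentially enriched outside transcription start sites. There were 4429 such regions at 0 h, 1629 at 24 h and 7845 at 240 h. Factor peaks were narrow, with median widths of 256 bp for C/EBPβ at 0 h, 300 bp for C/EBPβ at 6 h and 354 bp for GR. H3K9ac regions were broader, with medians of 1500 bp at 0 h, 1300 bp at 24 h and 1600 bp at 240 h. Median peak height was 18 in both C/EBPβ lists and 16 in the GR list. The median of the authors' average read count was 11 at 0 h, 9 at 24 h and 11 at 240 h. Each group was 1 library of unknown depth, so no value has a replicate error. The intervals below are 95% intervals of counting error.

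The first comparison asked how C/EBPβ occupancy changed between 0 and 6 h. The list at 6 h was 2.003-fold as long, and most sites of undifferentiated cells were listed again. Of the 10359 peaks at 0 h, 7385 (71.3%, 70.4 to 72.2%) overlapped a peak at 6 h, which was 131-fold the mean of random rotations. Another 2974 peaks (28.7%) had no counterpart in the 6 h list. Seen from 6 h, 7396 of 20746 peaks (35.7%, 35.0 to 36.3%) were already listed at 0 h, and 13350 (64.3%) were new.

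Stronger peaks recurred more often than weaker ones. Each list was divided by peak height into 4 classes of equal size. In the strongest class of the 0 h list, 92.9% (91.8 to 93.8%) overlapped a 6 h peak, against 50.9% (49.0 to 52.9%) in the weakest class, whose heights were 12 to 14. The difference was 41.9 percentage points (39.8 to 44.1). At 6 h, 64.3% of the strongest class and 17.4% of the weakest class overlapped a 0 h peak, a difference of 46.9 points (45.2 to 48.5) that was examined only after the lists had been seen. All 5 of the highest 0 h peaks were listed at 6 h. The highest lay on chromosome 17 at 44172943 to 44173324, with a height of 134 and a fold enrichment of 46.49, inside an H3K9ac 0 h region, and its highest 6 h counterpart had a height of 86. The peak on chromosome 15 at 56866968 to 56867748 was among the 5 highest at both times, with heights of 133 at 0 h and 99 at 6 h. All 5 of the highest 6 h peaks were also listed at 0 h and near a GR peak, the highest of them on chromosome 4 at 58425018 to 58425348 with a height of 112. Heights were not normalised between libraries here, and any scaling by the authors is not given. Without read totals the greater number of peaks at 6 h cannot be separated from a difference in depth.

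**Figure D1:**
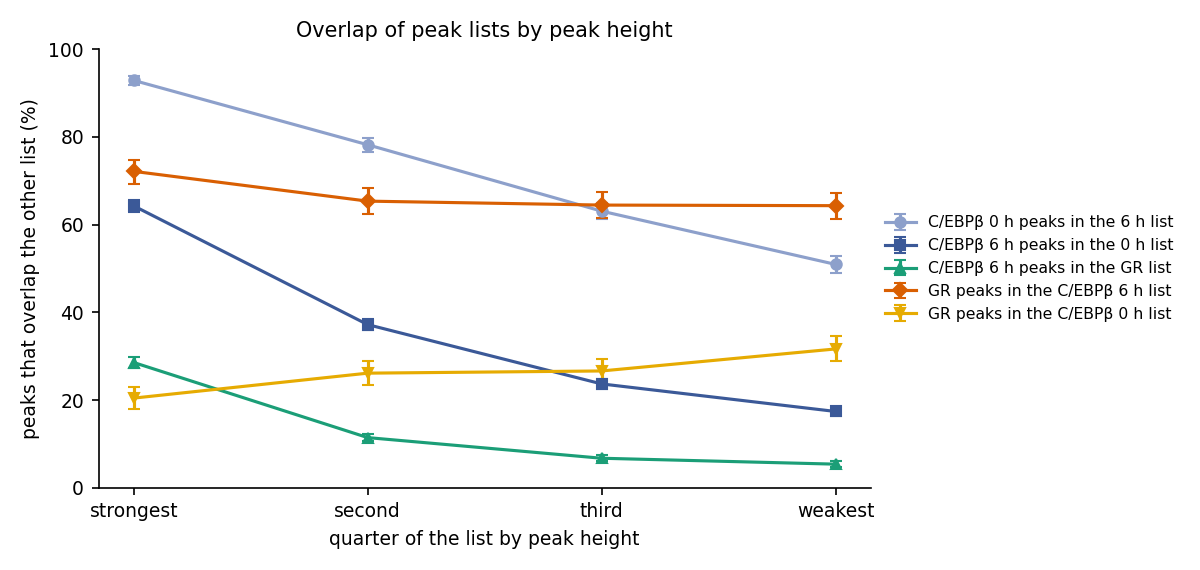
Share of peaks that overlap another list (%, y axis) in 4 equal classes of the list's own peak height (x axis, strongest to weakest), with 95% Wilson intervals as bars. Overlap of C/EBPβ lists falls from the strongest to the weakest class (92.9% to 50.9% for 0 h peaks), while GR peaks in the C/EBPβ 0 h list, a comparison added after the lists had been seen, go from 20.5% to 31.7%.

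The second comparison asked where GR bound relative to C/EBPβ at 6 h. GR lay mainly on C/EBPβ sites. Of 4007 GR peaks, 2668 (66.6%, 65.1 to 68.0%) overlapped a C/EBPβ peak at the same time, 100.3-fold the mean of random rotation. The C/EBPβ list of undifferentiated cells held 1051 of the GR peaks (26.2%, 24.9 to 27.6%), which was 85.1-fold the mean of random rotation. Rotation ignores where factors can bind, so neither fold measures a preference of GR for C/EBPβ sites. The 6 h list exceeded the 0 h list by 40.4 points (38.3 to 42.3). This interval treats the shares as independent, although both were taken over the same GR peaks. By list, 1036 GR peaks overlapped C/EBPβ at both times, 1632 at 6 h only, 15 at 0 h only and 1324 at neither. The lists differ in length, and with each C/EBPβ list limited to its 4007 strongest peaks 32.5% of GR peaks overlapped C/EBPβ at 6 h and 15.5% at 0 h.

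From the other side, 2706 of 20746 C/EBPβ 6 h peaks (13.0%, 12.6 to 13.5%) overlapped a GR peak. This share was 28.6% (27.4 to 29.8%) in the strongest class of C/EBPβ peaks and 5.40% (4.82 to 6.05%) in the weakest, a difference of 23.2 points (21.8 to 24.5). Of the C/EBPβ peaks shared with GR, 1650 (61.0%, 59.1 to 62.8%) were new at 6 h. New C/EBPβ peaks overlapped GR in 12.4% of cases and those already listed at 0 h in 14.3%, a difference of 1.92 points (0.954 to 2.90). The older peaks were higher, with a median height of 24 against 16. With the stronger peaks of each list alone, new means absent from the stronger 0 h peaks, and the difference was -1.77 points (-2.95 to -0.547). Some of those new peaks overlapped weaker 0 h peaks. The direction thus depends on the setting, in which the threshold and the classes changed together. Ranked by GR height, 72.2% of the strongest and 64.3% of the weakest class of GR peaks overlapped C/EBPβ at 6 h. That difference of 7.82 points (3.74 to 11.9) was 0.729 (-3.29 to 4.74) when GR peaks were ranked by fold enrichment. All 5 of the highest GR peaks overlapped a C/EBPβ 6 h peak, and 1 of them was near a C/EBPβ 0 h peak. The highest, on chromosome 19 at 21665798 to 21666271, had a height of 128 and a fold enrichment of 38.54.

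The third comparison set the H3K9ac lists side by side. No region of any H3K9ac list overlapped a region of another. The lists hold regions called at 1 time relative to another, so this count can be set by how they were made. The strongest 0 h region by average read count lay on chromosome 10 at 38512950 to 38514400 with a value of 32. The strongest 24 h region lay on chromosome 2 at 160493000 to 160498950 with a value of 18, and the strongest 240 h region on chromosome 19 at 44467550 to 44473250 with a value of 45. An FDR of 0 was listed for 50.4% of the 0 h regions, 17.6% of the 24 h regions and 45.3% of the 240 h regions.

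The fourth comparison asked whether regions that carried more H3K9ac at a given time lay near sites of early factor binding. The 24 h regions stood apart by their proximity to GR. A GR 6 h peak lay within 1 kb of 346 of 1629 regions at 24 h (21.2%, 19.3 to 23.3%), of 174 of 4429 at 0 h (3.93%, 3.40 to 4.54%) and of 181 of 7845 at 240 h (2.31%, 1.998 to 2.66%). These shares were 33.8-fold, 5.57-fold and 3.10-fold the mean of random rotation. The 24 h list exceeded the 0 h list by 17.3 points (15.3 to 19.4), a ratio of 5.41, and the 240 h list by 18.9 points (17.0 to 21.0), a ratio of 9.21.

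C/EBPβ at 6 h showed the same order with smaller ratios. Its excess at 24 h over 0 h went with the larger share of regions near GR, as given below. A C/EBPβ 6 h peak lay near 569 of the 24 h regions (34.9%, 32.7 to 37.3%), 1067 of the 0 h regions (24.1%, 22.9 to 25.4%) and 986 of the 240 h regions (12.6%, 11.9 to 13.3%). The 24 h list exceeded the 0 h list by 10.8 points (8.23 to 13.5) and the 240 h list by 22.4 points (19.96 to 24.8). With all lists limited to equal length these differences were 6.02 (3.97 to 8.08) and 7.06 points (5.07 to 9.08). C/EBPβ peaks of undifferentiated cells followed another order. They lay near 17.9% (16.8 to 19.0%) of the 0 h regions, 11.6% (10.1 to 13.2%) of the 24 h regions and 7.84% (7.27 to 8.46%) of the 240 h regions. The difference of the 24 h from the 0 h share was -6.28 points (-8.15 to -4.30). Its excess of 3.76 points over the 240 h list turned to -1.17 (-2.77 to 0.429) when all lists were limited to equal length.

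**Figure D2:**
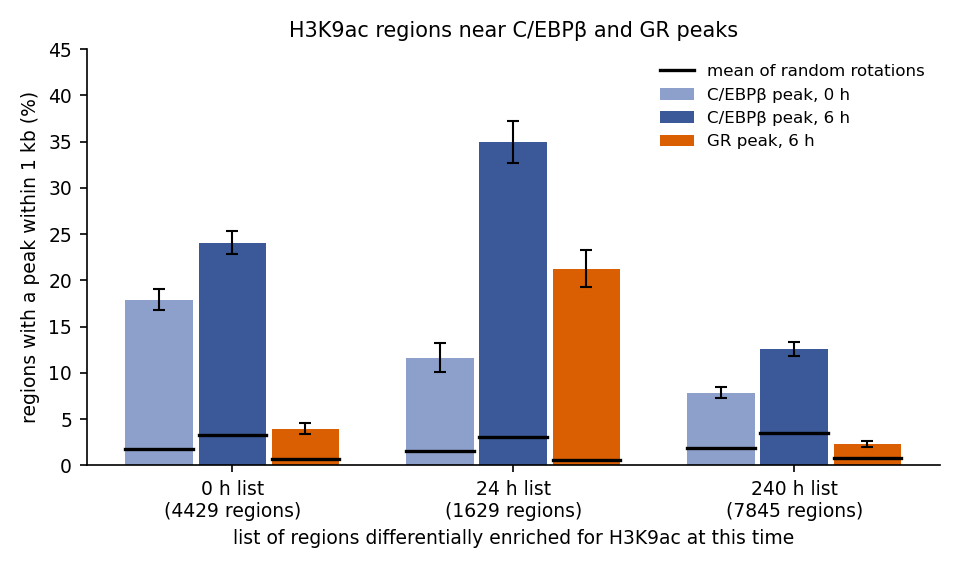
Share of H3K9ac regions with a factor peak within 1 kb (%, y axis) for the lists of 0, 24 and 240 h (x axis), with 95% Wilson intervals as error bars and the mean of 1000 random rotations as black lines. The 24 h regions show the highest bars for C/EBPβ at 6 h (34.9%) and GR (21.2%), and the 0 h regions the highest for C/EBPβ at 0 h (17.9%).

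Of the 24 h regions, 275 (16.9%) had both C/EBPβ and GR 6 h peaks within 1 kb, 294 (18.0%) had C/EBPβ alone, 71 (4.36%) had GR alone and 989 (60.7%) had neither. Both factors lay near 3.12% of the 0 h regions and 1.90% of the 240 h regions, and neither lay near 75.1% and 87.0% of them. C/EBPβ alone lay near 21.0% (19.8 to 22.2%) of the 0 h and 10.7% (10.0 to 11.4%) of the 240 h regions. The excess of the 24 h over the 0 h list near C/EBPβ 6 h peaks was thus counted in regions also near GR. Among regions near GR, similar shares had a C/EBPβ 6 h peak at each time. These were 79.3% (72.7 to 84.7%) at 0 h, 79.5% (74.9 to 83.4%) at 24 h and 82.3% (76.1 to 87.2%) at 240 h. The excess went with more 24 h regions being near GR, not with more C/EBPβ among them. This division was chosen after the lists had been examined. Within the 24 h list, the strongest of 4 classes by average read count lay near GR in 35.8% (31.3 to 40.5%) of cases and the weakest class in 16.0% (12.7 to 19.8%). The classes between had 17.9% and 15.2%. The average read count at 24 h had a median of 9 and quartiles of 9 and 10. Neighbouring classes thus share values and were split by FDR, then list order. The strongest and weakest classes had 5.14% and 2.26% in the 0 h list, and 3.36% and 1.73% in the 240 h list. Of the 5 strongest 24 h regions, 4 were near a GR peak. They included a region on chromosome 19 at 17014850 to 17018850, where the GR height was 103, and the chromosome 2 region, where it was 63. None of the 5 strongest regions at 0 h or at 240 h was near a GR peak, and 2 of the 5 at 0 h were near a C/EBPβ 0 h peak.

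A total of 262 GR peaks (6.54%) overlapped a C/EBPβ 6 h peak and lay near an H3K9ac 24 h region. The 3 strongest by GR height lay on chromosome 19 at 21665798 to 21666271, on chromosome 17 at 3174824 to 3175388 and on chromosome 5 at 66851588 to 66852056. Their GR heights were 128, 120 and 115, their C/EBPβ 6 h heights 36, 46 and 87, and none was near a C/EBPβ 0 h peak. The acetylated regions that held them spanned 21664850 to 21666600, 3173150 to 3181200 and 66850900 to 66853000.

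C/EBPβ 6 h peaks were then divided by their presence at 0 h and by overlap with GR, a division chosen after the lists had been examined. New C/EBPβ sites with GR were those most often near H3K9ac 24 h regions, with 185 of 1650 (11.2%, 9.78 to 12.8%). New sites without GR had 278 of 11700 (2.38%, 2.12 to 2.67%), a difference of 8.84 points (7.37 to 10.5). Sites already listed at 0 h had 7.86% (6.39 to 9.64%) with GR and 1.56% (1.28 to 1.90%) without. With the stronger peaks of each list alone, the classes were redefined by overlap with the stronger 0 h and stronger GR peaks. Some sites called new there overlapped weaker 0 h peaks. Sites with GR then had 15.4% when new and 12.5% when older, and sites without GR 3.597% and 1.71%. New exceeded older sites with GR by 3.35 points (1.07 to 5.54) over all peaks. Over the stronger ones, with the classes redefined, the difference was 2.97 (-1.77 to 7.19), within counting error. Near H3K9ac 0 h regions lay 7.58% and 8.44% of the older sites with and without GR, and 3.15% and 4.38% of the new ones. Near 240 h regions the 4 classes lay between 4.48% and 5.91%, and new sites with and without GR differed by 0.00622 points (-0.972 to 1.17). C/EBPβ peaks listed only at 0 h lay near 24 h regions in 10 of 2974 cases (0.336%, 0.183 to 0.618%), and 230 of 1000 random rotations gave as many. GR peaks outside the C/EBPβ 6 h list lay near 24 h regions in 6.20% (5.03 to 7.62%) of cases, against 9.82% (8.75 to 11.0%) of those inside it. The same direction was seen near 0 h regions (3.29% against 4.76%) and near 240 h regions (3.06% against 5.13%), so it was not particular to 24 h.

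**Figure D3:**
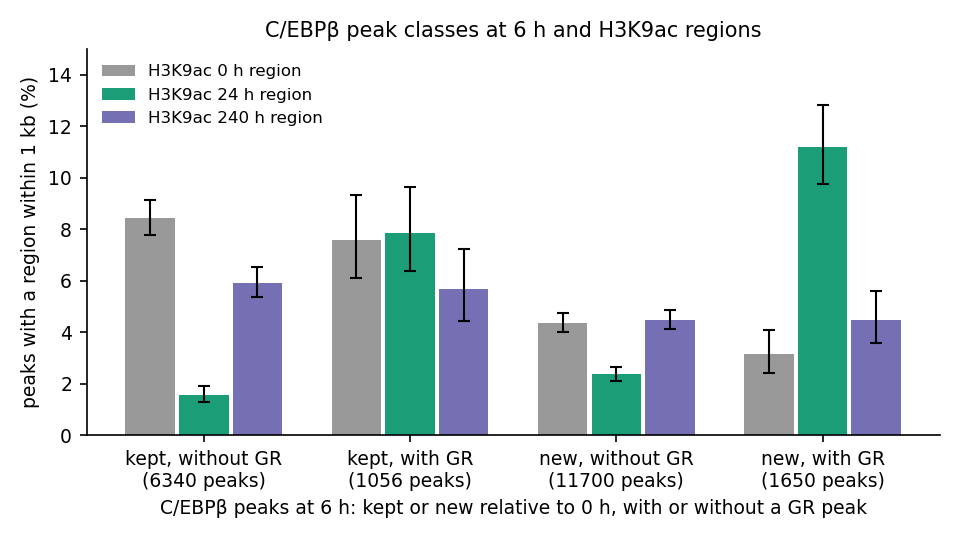
Share of C/EBPβ 6 h peaks within 1 kb of an H3K9ac region (%, y axis) for peaks also listed at 0 h (kept) or not (new), with or without a GR peak (x axis), with 95% Wilson intervals. The bar for 24 h regions is highest in the new sites with GR (11.2%) and lowest in the kept sites without GR (1.56%).

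Factor peaks were unevenly spread along the genome, which was not tested against random placement. The 100 kb window with most C/EBPβ 6 h peaks, on chromosome 17 from 79600000 to 79700000, held 19 of them against a genome mean of 0.792. It also held 6 C/EBPβ peaks at 0 h, 5 GR peaks and 7 H3K9ac 24 h regions, with no 0 h region and 1 region at 240 h. The next windows lay on chromosome 6, from 17000000 with 18 C/EBPβ 6 h and 7 GR peaks and from 115300000 with 17 C/EBPβ 6 h and 6 GR peaks, and each had 2 H3K9ac 24 h regions. GR peaks were densest on chromosome 6 from 129100000 to 129200000, with 11 GR peaks, 17 C/EBPβ 6 h peaks and no 24 h region. Its count of C/EBPβ 6 h peaks tied with that of the window from 115300000. A window on chromosome 19 from 33100000 followed with 8 GR peaks. The densest windows of H3K9ac 240 h regions lay on chromosome 11 from 53600000, chromosome 15 from 76800000 and chromosome 18 from 12000000. Each held 15 regions, no GR peak and at most 3 C/EBPβ 6 h peaks. With a genome mean of 0.153 GR peaks per window, most windows hold none. Their counts of C/EBPβ 6 h peaks were not below the genome mean of 0.792.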

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

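Under the alternatives fixed in advance, 22 shares stayed within their 95% intervals and 37 moved out of them, and 10 folds over random stayed within the share's interval, scaled to the fold, and 4 moved. Of the differences, 37 kept their direction and an interval without 0, whatever their size, and 1 reversed. Under those chosen after the data were examined (ranking by fold enrichment, and those for C/EBPβ 6 h peaks divided by GR and time and for the height classes added later), 8 shares stayed within and 28 moved, and 7 differences kept their direction, 2 lost their call and 1 reversed. No pairing of libraries was possible because each group is 1 library. The intervals for GR peaks in the C/EBPβ 6 h minus the 0 h list ignore that both shares come from the same GR peaks. The unknown depth limits all statements about peaks missing from a list.

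Requiring a longer overlap, measured against the shorter peak, or leaving out chromosome X, moved no share out of its interval. With centres within 1 kb, 72.9% of C/EBPβ 0 h peaks were in the 6 h list, 38.2% of 6 h peaks in the 0 h list, 69.8% of GR peaks in the C/EBPβ 6 h list, 14.7% of C/EBPβ 6 h peaks in the GR list and 29.1% of GR peaks in the C/EBPβ 0 h list. With the stronger peaks of both lists these were 68.4%, 34.2%, 52.3%, 10.2% and 16.1%, where fewer peaks could be met by construction. Uniform placement gave folds of 128.5 for C/EBPβ 0 h peaks in the 6 h list, and of 6.70, 10.6 and 3.28 for H3K9ac regions of 0, 24 and 240 h near C/EBPβ 6 h peaks.

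The shares of H3K9ac regions moved with the distance by construction. Near C/EBPβ 0 h, C/EBPβ 6 h and GR peaks in turn, direct overlap gave 14.1%, 18.9% and 2.94% at 0 h, 8.04%, 26.0% and 16.4% at 24 h, and 6.23%, 9.89% and 1.67% at 240 h. Within 10 kb they were 40.1%, 51.3% and 13.6% at 0 h, 36.6%, 66.4% and 40.4% at 24 h, and 25.6%, 35.2% and 8.46% at 240 h. With the stronger factor peaks they were 10.002%, 14.3% and 1.49% at 0 h, 6.14%, 24.98% and 14.9% at 24 h, and 4.38%, 7.51% and 1.15% at 240 h.

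Near 24 h regions, C/EBPβ 6 h peaks that were new with GR, new without, older with GR and older without had 8.79%, 1.65%, 6.16% and 1.14% by direct overlap, 19.3%, 6.50%, 16.8% and 5.69% within 10 kb, and 15.4%, 3.597%, 12.5% and 1.71% with the stronger peaks. The sizes of differences moved more than their direction. For H3K9ac 24 h minus 0 h regions they ranged from -6.24 to -3.41 points near C/EBPβ 0 h, 6.02 to 15.1 near C/EBPβ 6 h and 13.4 to 26.8 near GR peaks. For 24 h minus 240 h regions they ranged from 7.06 to 31.2 near C/EBPβ 6 h, 13.7 to 31.9 near GR and -1.17 to 11.1 near C/EBPβ 0 h peaks, where the lowest came with equal list lengths. For GR peaks in the C/EBPβ 6 h minus the 0 h list the range was 16.9 to 40.6. With 10 height classes the strongest exceeded the weakest by 36.2 points for C/EBPβ 6 h peaks in the GR list, 49.9 for C/EBPβ 0 h in the 6 h list, 62.3 for the reverse and 13.3 for GR in the C/EBPβ 6 h list. The difference between the strongest and weakest GR classes in overlap with C/EBPβ 6 h was 0.729 points when ranked by fold enrichment. With the stronger peaks, older and new were judged by the stronger 0 h peaks alone, and GR by the stronger GR peaks. In that setting overlap with GR of older minus new C/EBPβ 6 h peaks was -1.77 points. The share near 24 h regions of new minus older peaks with GR was 2.97. The cause of these reversed or lost differences was not tested.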

Other observations

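The tests of nearness to acetylated regions of the other times and of GR peak width were chosen only after the result was seen. So were the counts by chromosome, the distances between H3K9ac lists, and the overlap of GR height classes with C/EBPβ at 0 h. The division of C/EBPβ peaks by GR and by time was also chosen then, as was that of H3K9ac regions by the factors near them.

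Chromosome 6 held 9.73% of C/EBPβ 6 h peaks, 11.7% of GR peaks, 10.1% (9.24 to 11.0%) of H3K9ac 0 h regions and 9.71% (9.08 to 10.4%) of 240 h regions, but 5.22% (4.24 to 6.41%) of 24 h regions, with 5.70% of the listed genome length. Chromosome X, with 6.32% of the length, held 2.32% of C/EBPβ 6 h peaks, 2.37% of H3K9ac 0 h regions, 1.47% of 24 h regions and 0.637% of 240 h regions. Chromosome 19, with 2.33% of the length, held 4.39% of C/EBPβ 6 h peaks, 5.34% of GR peaks and 2.76% of 24 h regions. Chromosome 15, with 3.94% of the length, held 6.32%, 7.09% and 5.34% of them. Copy number of these chromosomes in the cells was not analysed here.

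A 0 h region lay within 10 kb of 131 of the 1629 H3K9ac 24 h regions (8.04%) and within 1 kb of 37 (2.27%), and a 240 h region within 10 kb of 125 (7.67%) and within 1 kb of 15 (0.921%). Of the 4429 regions at 0 h, 264 (5.96%) had a 240 h region within 10 kb and 24 (0.542%) within 1 kb. These counts are not set against random rotation, because rotated lists can overlap and the deposited ones do not. Of the C/EBPβ 0 h peaks absent from the 6 h list, 6.83% lay near 0 h regions and 5.72% near 240 h regions.

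H3K9ac 24 h regions lay near GR 6 h peaks more often (21.2%) than 0 h or 240 h regions. In 100 draws of 0 h and 240 h regions, matched to the 24 h list in width and average read count, the share reached at most 3.24%. Region width is opposed as the cause, since the 24 h regions were also the narrowest, with a median of 1300 bp against 1500 and 1600 bp. Read density could not be decided, because average read counts from libraries of unknown depth cannot be equated. Dilution of the longer lists by weak regions is also opposed, since their strongest regions, in equal number, reached at most 5.03%. Depth and the unnamed caller of the H3K9ac lists stay open, and no biological explanation was tested.

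C/EBPβ 6 h peaks shared with GR lay near 24 h regions more often (9.90%) than the others (2.09%). Weighting the others to the heights of the shared peaks gave 2.29%, which is against C/EBPβ height as the cause. Near 0 h regions the shared peaks differed by -0.926 points (-1.75 to 0.0125), and near 240 h regions by -0.0314 (-0.855 to 0.904). The excess was thus not seen near regions called at the other times. Regions that did not differ between times are in no list, so nearness to acetylated regions in general could not be tested. No biological explanation was tested.

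Weaker GR peaks overlapped C/EBPβ 0 h peaks more often (31.7% in the weakest of 4 height classes) than stronger ones (20.5%). Width is opposed as the cause, since the difference in median width of the weakest from the strongest class was -99 bp. Weak GR signal at strong C/EBPβ sites could not be decided, with C/EBPβ 0 h heights 5.38 percentile points higher (-4.08 to 10.8) under the weakest GR class, an interval that holds 0. No biological explanation was tested.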
